A study of Mus musculus with 9 samples.

How the data were processed

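Total RNA from mouse midbrain was sequenced in 9 libraries, 3 in each of 3 groups. The groups, per the labels, were wild-type B6C3F1/J mice given vehicle, mice homozygous for the M83 transgene given vehicle, and M83 mice given myriocin. M83 mice carry human alpha-synuclein with the A53T substitution under mouse Prnp (prion protein) sequences, and myriocin inhibits serine palmitoyltransferase, the enzyme that starts sphingolipid synthesis. Dose, length of treatment, age and sex were not given in the sources used here. Per the labels' protocols, RNA was extracted with TRIzol, ribosomal RNA was depleted and libraries were made with a stranded total RNA kit.

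The authors deposited 1 table of raw counts per gene, whole numbers that were not normalized, with 57010 Ensembl gene identifiers and 9 columns, each matched to a sample by its name. Per the submitters' processing notes, fastp, STAR 2.7.3a and featureCounts from Subread 2.0.1 were used with the GRCm39 genome. The annotation release, the strand setting and the handling of reads that map to several places are not given in the sources used here. Counts of overlapping genes, antisense genes and near-identical copies are therefore uncertain. Symbols, biotypes and chromosomes were looked up by identifier in a GENCODE annotation of another build, GRCm38, which gave a symbol to 52029 identifiers and left 4981 without one. No coordinates are given for that reason. Identifiers without a symbol held between 7.62% and 9.84% of the counts in a library and stayed in the tests.

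Total counts ran from 30222824 to 32783753 per library, so that 3 counts, the number that an observed count of 0 allows, corresponded to between 0.0915 and 0.0993 CPM, counts scaled to library totals. Such floors cover counting error only, since reads without molecular identifiers are not independent molecules. No pair of libraries within a group agreed within sampling noise: the chi-square per degree of freedom of their counts was between 16.2 and 57.0, so each library counted as 1 replicate. The labels number the samples within each group without naming animals, and the p-values measure the spread between these libraries.

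Tests were run in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, which left 21067 genes holding at least 99.8% of the counts of every library, and libraries were scaled with TMM. A single model with the 3 groups was fitted to all 9 libraries, the common biological coefficient of variation was 0.215, and pairs of groups were compared with edgeR's quasi-likelihood test. Adjusted p-values are Benjamini-Hochberg values over all tested genes, with 0.05 as the threshold and no fold threshold, and are called quasi-likelihood adjusted p. CPM values use the TMM-scaled totals and are given as mean ± SD of 3 libraries, and log2 fold changes carry their standard error (SE). A fold against a group with 0 counts in every library was computed against a floor of 3 counts over the group.

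Before the data were examined, 65 lists of genes were written, for pathways, cell types, neighbouring brain regions and RNA quality, and 63 of them had at least 5 measured genes. They were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, two-sided, adjusted over the 63 lists. Camera compares a list with all other genes. The same test with a correlation estimated from the libraries, and fry, a rotation test of whether a list's genes move one way on balance, were run as alternatives. A list's score in a library is the mean deviation of its genes' log2 CPM from their mean over the 9 libraries.

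The genes named were fixed by a rule before the data were examined. It covers Snca and Prnp, and, of the genes past the threshold, the 10 largest rises and 10 largest falls with a mean CPM of at least 1, a symbol that is not a clone or model name and no overlap between the libraries of the groups. Where fewer than 10 genes passed, the 10 with the smallest p that met the other conditions are named as not passing. Up to 4 members with the smallest p come from each list that passed and from the lists of sphingolipid synthesis, sphingolipid breakdown, dopaminergic neurons, astrocytes, homeostatic microglia, disease-associated microglia and oligodendrocytes. Members of any list past the gene threshold could also be named. Genes outside the rule are said to have been chosen after their values were seen.

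Alternatives set before the data were examined were DESeq2 1.42.0 on all genes with counts, limma-voom with quality weights, RLE and upper-quartile scaling, no filter on low counts, a filter of CPM over 1 in at least 3 libraries, only the 2 groups compared in the fit, the replicate number as a block, and leaving out each library in turn. Alternatives chosen after seeing the data were scores of the dopaminergic neuron and thalamus and hypothalamus lists as 2 covariates, leaving out the 3 libraries with Th under 15 CPM, leaving out A53T vehicle libraries 1 and 2, DESeq2 on the genes kept by the filter, for the numbers of changed genes, and, for opposed changes, counting the 4 Ccl21 copies as 1 gene. Groups that share a set of control libraries were also simulated without effects, 20 times, from negative binomial counts. Near-identical copies were searched among the annotated transcripts with BLAST+ 2.17.0, at 97% identity over at least 100 bases. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

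The steps were tested on simulated counts with 200 changed genes. For A53T vehicle against wild type, over 20573 simulated genes, 4, 30, 42 and 49 of 50 genes changed by 0.5, 1, 2 and 3 on the log2 scale were recovered, with 5 calls among unchanged genes. For myriocin against A53T vehicle, over 20549 genes, the numbers were 5, 29, 43 and 48, with 8 such calls. For myriocin against wild type, over 20456 genes, they were 6, 25, 44 and 49, with 8 such calls. In each comparison 3 of 3 shifted lists and 0 of the unshifted lists passed; the simulated genes were independent of each other.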

Results

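Gene expression was measured by total RNA sequencing of the midbrain in 3 groups of mice. Wild-type mice given vehicle, A53T mice given vehicle and A53T mice given myriocin contributed 3 libraries each. The A53T mice are of the M83 line, a Parkinson's disease model in which human A53T alpha-synuclein is expressed from mouse Prnp sequences. Total counts were 32374770, 32209918 and 30222824 in wild-type replicates 1 to 3, 32783753, 31877252 and 32681144 in A53T vehicle, and 32349943, 30769378 and 31147101 in A53T myriocin. Of the 57010 genes in the table, 21067 were tested.

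The transgene was visible in every A53T library. Prnp (ENSMUSG00000079037, chromosome 2), the prion protein gene, measured 709 ± 45.5 CPM in wild type (SD, n = 3), 5700 ± 322 CPM in A53T vehicle and 5239 ± 286 CPM in A53T myriocin. It rose 8.04-fold in A53T vehicle (log2 fold change 3.01, SE 0.10, quasi-likelihood adjusted p = 1.63e-07) and 7.39-fold in A53T myriocin (2.89, SE 0.10, quasi-likelihood adjusted p = 2.37e-07). Snca (ENSMUSG00000025889, chromosome 6), the mouse alpha-synuclein gene, measured 85.3 ± 21.8 CPM in wild type, 227 ± 7.85 CPM in A53T vehicle and 233 ± 31 CPM in A53T myriocin. It rose 2.66-fold (log2 fold change 1.41, SE 0.17, quasi-likelihood adjusted p = 0.0162) and 2.73-fold (1.45, SE 0.17, quasi-likelihood adjusted p = 0.0141). Reads of human SNCA were not told apart from those of mouse Snca in the counts. Lamr1-ps1 (ENSMUSG00000081229), a processed pseudogene with no annotated gene between it and Prnp, was chosen after its values were seen. It had 0 counts in each wild-type library and 63.5 ± 7.55 and 61.6 ± 1.69 CPM in A53T vehicle and A53T myriocin, at least 2040-fold and 1975-fold higher (floor of 3 counts over the wild-type group). Between the 2 A53T groups, Prnp and Snca had fold changes of 0.919 and 1.03 (quasi-likelihood adjusted p = 0.614 and 0.951).

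Prnp and Lamr1-ps1 passed in every fit that left out 1 library. The call of Snca in A53T vehicle ended without wild-type replicate 3 (quasi-likelihood adjusted p = 0.0686) or A53T vehicle replicate 1, 2 or 3 (0.113, 0.0684 and 0.0911). In A53T myriocin it ended without wild-type replicate 3 (0.0762) or A53T myriocin replicate 1 or 3 (0.0861 and 0.0926), and the log2 fold change of Snca stayed between 1.22 and 1.57 in all of these fits.

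**Figure D1:**
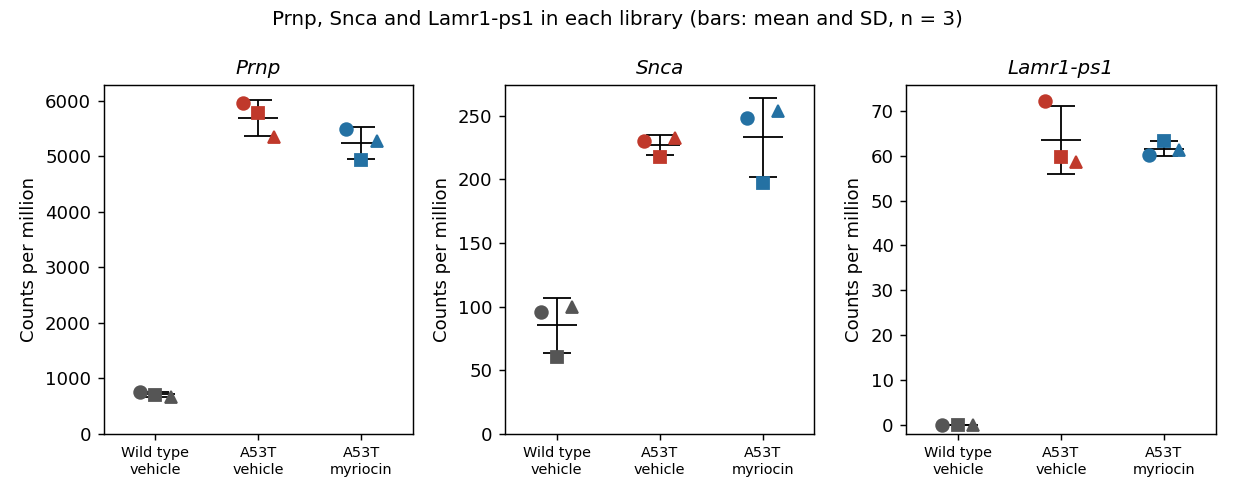
CPM (vertical axes, linear) of Prnp, Snca and Lamr1-ps1 in the 9 libraries; circles, squares and triangles are replicates 1, 2 and 3, and bars give mean and SD of 3 libraries. All 6 A53T libraries lie above the 3 wild-type libraries in each panel, with Lamr1-ps1 at 0 in wild type.

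Markers of midbrain cell groups differed widely between libraries of the same group. Th, tyrosine hydroxylase, measured 5.78, 13.2 and 188 CPM in wild-type replicates 1 to 3, 9.39, 30.3 and 69.9 CPM in A53T vehicle, and 141, 24.7 and 86.6 CPM in A53T myriocin. The dopamine transporter gene Slc6a3 followed the same order, and Tph2, the serotonin-synthesising enzyme of raphe neurons, was highest in wild-type replicate 2. Prkcd, strong in thalamus, measured 754 ± 242 CPM in A53T vehicle, 233 ± 239 CPM in wild type and 158 ± 220 CPM in A53T myriocin (SD, n = 3). These 4 genes were chosen after their values were seen, and none passed the threshold in any comparison. The dopaminergic neuron list (24 genes) had 1 member higher and 23 lower in A53T vehicle than in wild type (median log2 fold change -0.84, camera adjusted p = 0.781). Its 4 members with the smallest p were Sox6, Calb1, Gch1 and Pitx3, of which Calb1 alone was higher (log2 fold change 0.54, SE 0.24). In A53T myriocin against A53T vehicle 22 of the 24 members were higher (median 0.79, camera adjusted p = 0.181), and against wild type 12 were higher and 12 lower (camera adjusted p = 0.221, toward higher values, with a median of 0.03 and a mean of -0.06). These counts rest on single libraries. Without wild-type replicate 3, 18 of the 24 were higher in A53T vehicle (median 0.58, camera adjusted p = 0.0119) and 24 of 24 in A53T myriocin (0.97, 1.56e-09), both against wild type. Without wild-type replicate 1, 23 of the 24 were lower in A53T vehicle (-1.21, 0.0181) and 23 in A53T myriocin (-0.43, 0.367). Without wild-type replicate 2 or A53T myriocin replicate 1, 19 and 22 were lower in A53T myriocin than in wild type (-0.24, 0.895 and -0.40, 0.892), and without A53T myriocin replicate 2, 16 were higher (0.17, 0.0197). Without A53T vehicle replicate 1 the test, not the median (-0.56), turned toward higher values in A53T vehicle against wild type (0.878). Between the A53T groups the median fell from 0.79 to 0.23 without A53T myriocin replicate 1 (17 of 24 higher, 0.584) and to 0.52 without A53T vehicle replicate 2, and the list passed without A53T vehicle replicate 3 (0.0349) or A53T myriocin replicate 2 (0.0164).

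**Figure D2:**
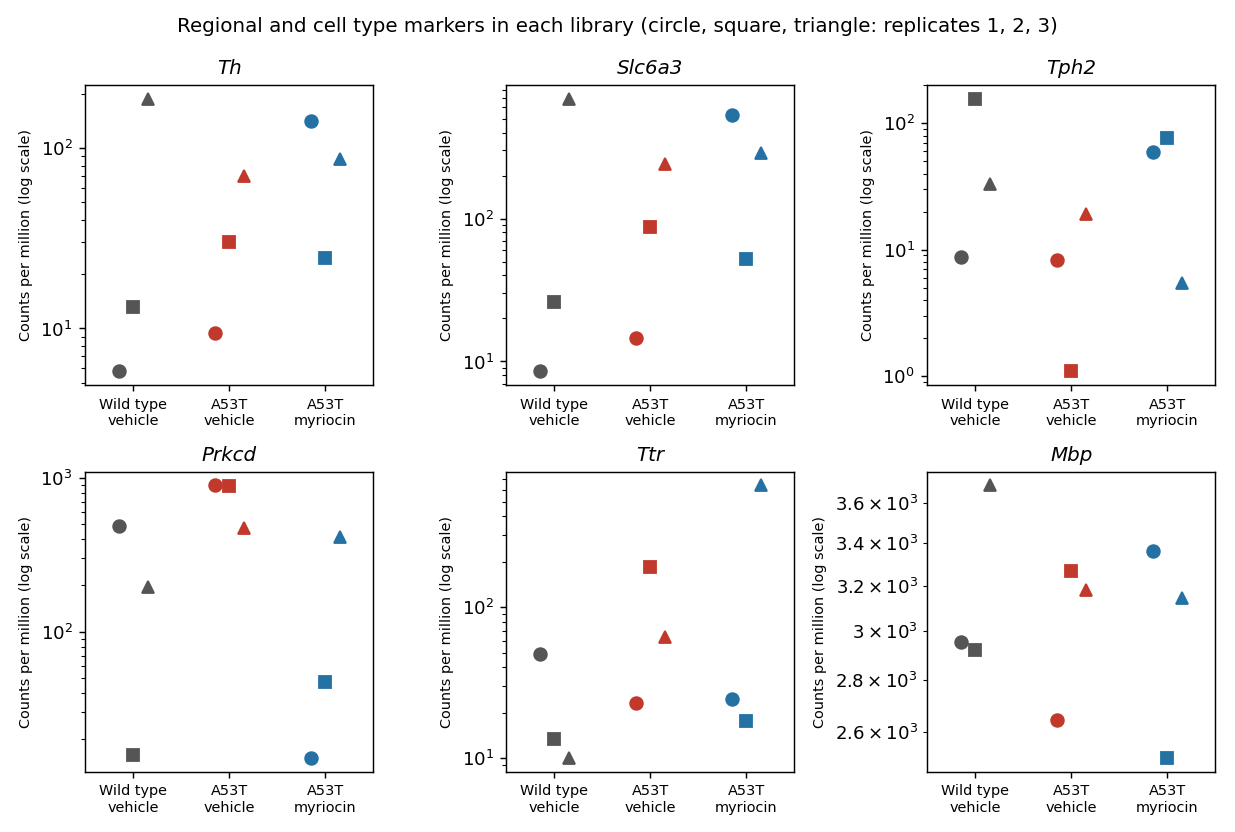
CPM (vertical axes, log scale) of 6 markers in the 9 libraries: Th and Slc6a3 (dopaminergic neurons), Tph2 (serotonergic neurons), Prkcd (thalamus), Ttr (choroid plexus) and Mbp (myelin); circles, squares and triangles are replicates 1, 2 and 3. Th ranges from 5.78 to 188 CPM among the wild-type libraries alone.

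The comparison of A53T vehicle with wild type asks what differs between the transgenic and the wild-type midbrain. Outside the transgene, few genes of known function changed. Strain segments may also differ between the A53T and wild-type mice, so these changes need not come from the transgene. Pttg1, securin, which restrains sister chromatid separation, fell 18.3-fold from 16.2 ± 1.72 to 0.878 ± 0.549 CPM (log2 fold change -4.19, SE 0.40, quasi-likelihood adjusted p = 0.0031). Gbp11, of the interferon-inducible guanylate-binding protein family and annotated as a polymorphic pseudogene, fell 2.89-fold from 5.52 ± 0.384 to 1.91 ± 0.275 CPM (-1.53, SE 0.20, quasi-likelihood adjusted p = 0.0173). Ccl21b, a chemokine gene, rose 3.31-fold from 1.83 ± 0.270 to 6.07 ± 0.470 CPM (1.73, SE 0.20, quasi-likelihood adjusted p = 0.0124). Its transcript has 4 near-identical copies, and 3 of them, Gm21541, Gm13304 and Gm10591, rose as well (chosen after their values were seen), so the reads of this family cannot be assigned to a single gene.

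In all, 16 genes passed, 8 higher and 8 lower in A53T vehicle, and 2054 (9.75%) had an unadjusted p under 0.05 where chance gives 1053. The 7 genes not yet named were chosen after their values were seen. Klk1b24, of the kallikrein family, fell from 1.82 ± 0.406 to 0.0109 ± 0.0190 CPM, 2610507I01Rik from 9.65 ± 0.344 to 1.05 ± 0.316 CPM, and Gm8885, Gm12892, Gm12977 and Gm42765 fell too, while Gm15772, a near-identical copy of the ribosomal protein gene Rpl26, rose from 183 ± 20.7 to 346 ± 21.5 CPM. DESeq2, run on all genes with counts, called 93 genes (90 with the filter on low counts, chosen after seeing the data) and a fit without the filter on low counts 135; limma-voom called 25. The number of genes was 21, 10 and 4 without wild-type replicates 1, 2 and 3, and 6, 9 and 7 without A53T vehicle replicates 1, 2 and 3. Gbp11 was lost without wild-type replicate 2 or 3 or any A53T vehicle replicate (quasi-likelihood adjusted p between 0.0598 and 0.144), and Ccl21b without wild-type replicate 3 or any A53T vehicle replicate (0.0557 to 0.0832), while Pttg1 passed in all 6 of these fits. Pttg1 did not pass without A53T vehicle replicates 1 and 2 together (log2 fold change -3.40, adjusted p = 0.153), nor without the 3 libraries with Th under 15 CPM (-4.05, 0.534), both alternatives chosen after seeing the data.

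Of the 63 gene lists, 6 passed in A53T vehicle against wild type, 4 higher and 2 lower, by camera with its preset correlation. With a correlation estimated from the libraries all 6 had adjusted p = 0.99, and none passed with fry (smallest adjusted p 0.264). Thalamus and hypothalamus markers shifted most: 20 of 25 members were higher (median log2 fold change 1.10, camera adjusted p = 0.0063), among them Rora at 739 ± 311 against 324 ± 155 CPM and Slitrk6 at 67.8 ± 25.1 against 25.4 ± 15.3 CPM. Postsynaptic receptor genes were higher for 26 of 35 members (median 0.18, camera adjusted p = 0.0063). Gabbr1, a GABA-B receptor subunit, measured 859 ± 150 against 591 ± 63.2 CPM and Grm1, a metabotropic glutamate receptor, 297 ± 80.7 against 150 ± 63.1 CPM, while the GABA-A subunit genes Gabra2 and Gabra5 were lower. Axon cytoskeleton genes were higher for 23 of 27 members (median 0.12, camera adjusted p = 0.0076), such as Tubb3 at 607 ± 43.5 against 484 ± 6.98 CPM, and nuclear-encoded respiratory chain genes for 52 of 64 (median 0.06, camera adjusted p = 0.00868), such as Ndufs3 and Atp5b. Of these 4 lists only the axon list had scores that did not overlap between the groups. Wild-type replicate 1 scored 0.715 on the thalamus list, against 0.337 to 1.31 in A53T vehicle. It scored 0.143 on the postsynaptic list, above A53T vehicle replicate 3 (0.0373). On the respiratory chain list wild-type replicate 2 (0.0898) lay above every A53T vehicle library (highest 0.0520).

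The lists that shifted to lower values, by the preset correlation alone, were interferon response genes, with 25 of 30 members lower (median -0.29, camera adjusted p = 0.00567), and nuclear long non-coding RNAs, a list of RNA quality, with 11 of 12 lower (median -0.28, camera adjusted p = 0.00625). Ifi44 measured 0.410 ± 0.277 against 1.36 ± 0.434 CPM, Parp14 4.10 ± 0.207 against 6.47 ± 0.446 CPM, and Malat1 2549 ± 420 against 3611 ± 332 CPM. Markers of border macrophages and neutrophils (12 of 12 lower, median -0.45), mural cells and fibroblasts (16 of 19, -0.44) and endothelium (17 of 20, -0.19) moved the same way without passing (camera adjusted p = 0.0845, 0.0815 and 0.121). No member of these 6 lists passed among all genes tested. Adjusted over the list alone, 1 member of the postsynaptic receptor list passed and 0 of the other 5 lists. At an unadjusted p under 0.05, 2 lists passed with an estimated correlation and 2 with fry. The nuclear RNA list passed in every fit that left out 1 library. The interferon list was lost without wild-type replicate 1 (camera adjusted p = 0.0508). The postsynaptic list was lost without wild-type replicate 3 (0.0559) or A53T vehicle replicate 1 (0.0531), and the axon list without the latter (0.0531). The thalamus list was lost without wild-type replicate 2 (0.0651) or A53T vehicle replicate 3 (0.110). The respiratory chain list was lost without wild-type replicates 1 or 3 (0.311 and 0.123) or A53T vehicle replicate 3 (0.0754). The number of lists was 11 without wild-type replicate 2, 12 without A53T vehicle replicate 3 and 4 without A53T vehicle replicate 1.

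The comparison of A53T myriocin with A53T vehicle asks what the inhibitor changes in the transgenic midbrain. Genes of sphingolipid synthesis, the pathway that myriocin blocks, differed by less than the spread allowed a call: of 29 members 16 were higher and 13 lower (camera adjusted p = 0.376, toward lower values, with a median of 0.02 and a mean of -0.05). Sptlc2, a subunit of serine palmitoyltransferase, measured 80.5 ± 7.36 CPM with myriocin and 116 ± 24.6 CPM with vehicle (log2 fold change -0.53, SE 0.17, quasi-likelihood adjusted p = 0.228), against 80.7 ± 13.4 CPM in wild type. A53T vehicle replicates 1 to 3 measured 133, 129 and 88.2 CPM and A53T myriocin replicate 3 measured 89.0 CPM, so the groups overlapped. The higher vehicle mean of Sptlc2 thus rests on replicates 1 and 2. The glycosphingolipid enzyme genes B4galt5, St3gal5 and St8sia1 measured 25.6 ± 3.65, 29.8 ± 6.29 and 57.9 ± 4.27 CPM with myriocin and 39.7 ± 6.13, 46.5 ± 8.30 and 77.8 ± 11.7 CPM with vehicle. Adjusted over the list alone, 3 of the 29 members passed. Of the 26 sphingolipid breakdown genes 14 were higher and 12 lower (camera adjusted p = 0.993); Sgpp2 measured 32.4 ± 3.39 against 48.4 ± 9.18 CPM and Asah1, acid ceramidase, 94.8 ± 3.86 against 79.5 ± 4.35 CPM.

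No gene passed the threshold by edgeR's quasi-likelihood test in this comparison; the smallest adjusted p was 0.211, and 2767 genes (13.1%) had an unadjusted p under 0.05 where chance gives 1053. The count depended on the tool and the filter. limma-voom called 0 genes, DESeq2 572 (66 higher and 506 lower with myriocin) on all genes with counts and 587 on the 21067 genes kept by the filter (chosen after seeing the data), and edgeR without the filter on low counts 702 (80 higher and 622 lower). Without A53T vehicle replicate 3 it was 92 (6 higher and 86 lower), without A53T vehicle replicate 2 it was 1, and in the other 4 fits without 1 library it was 0. Of the 10 named genes with the smallest p, which did not pass, Reln, the gene of the secreted protein reelin, measured 133 ± 31.1 against 68.5 ± 5.39 CPM and Lmo3 55.2 ± 6.83 against 30.2 ± 5.18 CPM. The other 8 had lower means with myriocin: Cpne4 (34.1 ± 8.87 against 100 ± 28.1 CPM), Prox1 (24.1 ± 4.32 against 63.5 ± 17.4 CPM), Reps2, Inpp5j, Tenm1, Sema7a, Dpp9 and Blzf1. The rule that picked them asks for groups that do not overlap, which chance gives for 10% of genes at 3 against 3.

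By camera with its preset correlation 16 gene lists passed in this comparison, 9 toward higher and 7 toward lower values with myriocin. With an estimated correlation all 16 had adjusted p = 0.909, and none passed with fry (smallest adjusted p 0.138). Lower, by the preset correlation alone, were 27 of 35 postsynaptic receptor genes (median log2 fold change -0.36, camera adjusted p = 1.21e-06), 24 of 30 synaptic vesicle genes (-0.18, 0.000308), 20 of 28 calcium signalling genes (-0.34, 0.00394) and 18 of 27 axon cytoskeleton genes (-0.13, 0.00394). The NMDA receptor genes Grin2a and Grin2b measured 158 ± 23.3 and 167 ± 59.2 CPM with myriocin against 287 ± 69.8 and 546 ± 202 CPM, the active zone gene Bsn 63.9 ± 15.3 against 162 ± 54.3 CPM, Atp2b1, a plasma membrane calcium pump, 379 ± 141 against 891 ± 232 CPM, and Map1a 555 ± 94.1 against 885 ± 127 CPM. None of these members passed among all genes tested. Adjusted over the list alone, 18, 9, 13 and 5 members of the 4 lists passed. The 4 lists were picked from the same libraries, so these counts are no separate support for changes in single genes. Thalamus and hypothalamus markers moved with these lists and were lower for 21 of 25 members (-1.27, camera adjusted p = 0.000734), such as Rora at 208 ± 116 against 739 ± 311 CPM. Clock genes were lower for 15 of 18 members (-0.24, 0.00394), such as Hlf and Rorb, and mitochondrially encoded genes for 11 of 13 (-0.20, 0.0121), such as mt-Nd5 at 116 ± 17.9 against 161 ± 18.4 CPM. Of these 3 lists 0, 5 and 2 members passed adjusted over the list alone. The score of the mitochondrially encoded list was -0.0285, 0.129 and -0.727 in A53T myriocin replicates 1 to 3 and -0.0738 to 0.270 with vehicle. Only replicate 3 lay below the vehicle libraries. In 6 of the 7 lower lists the scores of the 2 groups did not overlap. In the clock list the margin was small, 0.0185 in the lowest vehicle library against 0.0170 in A53T myriocin replicate 3. The 7 lists were picked for a shift between these same libraries, so the lack of overlap is no separate support. With regional scores in the fit, chosen after seeing the data, the calcium signalling (-0.18, camera adjusted p = 0.131), clock (-0.15, 0.249) and thalamus lists (0.688), the latter itself a score, were lost.

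The 9 lists toward higher values also passed by the preset correlation alone (adjusted p = 0.909 with an estimated correlation, and none with fry), and in none of them did the scores of the 2 groups separate. A53T myriocin replicate 2 scored no higher than the highest A53T vehicle library in 7 of the 9, and replicate 3 in 3. Interferon response genes were higher for 28 of 30 members (median log2 fold change 0.49, camera adjusted p = 1.63e-06), with Ifit3 at 36.8 ± 7.94 against 23.6 ± 3.37 CPM and Irf9 at 11.8 ± 1.73 against 7.79 ± 0.949 CPM; the list's score was 0.541, -0.209 and 0.238 in A53T myriocin replicates 1 to 3 and -0.428 to -0.124 with vehicle. Cytosolic ribosome genes were higher for 72 of 75 (0.14, 2.80e-06), with Rpl3 at 819 ± 20.2 against 700 ± 39.4 CPM, but the median turned to -0.0049 (camera adjusted p = 0.751) without A53T vehicle replicates 1 and 2, an alternative chosen after seeing the data. Border macrophage and neutrophil markers were higher for 12 of 12 (0.88, 0.0022), such as Cd163, endothelial markers for 18 of 20 (0.33, 0.00398), such as Ly6c1 at 21.4 ± 1.10 against 14.6 ± 1.60 CPM, and mural cell and fibroblast markers for 17 of 19 (0.75, 0.0111), such as Acta2. Reactive astrocyte genes were higher for 22 of 22 (0.49, 0.0151), antigen presentation genes for 17 of 18 (0.34, 0.0205), nuclear long non-coding RNAs for 11 of 12 (0.24, 0.0151) and cell cycle genes for 18 of 22 (0.30, 0.0228), with C3, B2m, Mirg and Mki67 among them. Adjusted over the list alone, 7 interferon genes and 1 nuclear RNA passed, and 0 of the other 7 lists. Homeostatic microglia genes did not pass (19 of 24 higher, camera adjusted p = 0.271; C1qb 29.1 ± 14.9 against 13.2 ± 2.01 CPM), nor did complement (0.0809), NF-kB cytokine (0.271), lymphocyte (0.436), disease-associated microglia (22 of 27 higher, 0.113), astrocyte (16 of 20 higher, 0.318) or oligodendrocyte genes (10 of 24 higher, 0.637).

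At an unadjusted p under 0.05 camera with an estimated correlation and fry passed 1 and 7 lists. The interferon, ribosome, synaptic vesicle, postsynaptic and axon lists passed in each fit that left out 1 of the 6 libraries, though the ribosome list did not without both A53T vehicle replicates 1 and 2. The number of lists fell to 8 without A53T myriocin replicate 1, of which 7 were among the 16, and rose to 28 without A53T myriocin replicate 2. The lists lost without A53T myriocin replicate 1 were antigen presentation (camera adjusted p = 0.553), clock (0.148), calcium signalling (0.0616), cell cycle (0.0708), reactive astrocytes (0.223), border macrophages (0.192), endothelium (0.237), mural cells (0.303) and nuclear RNAs (0.0515). Without A53T myriocin replicate 3 the mitochondrially encoded (0.694), antigen presentation (0.0900), cell cycle (0.165), reactive astrocyte (0.173) and border macrophage (0.0629) lists were lost. Without A53T myriocin replicate 2 the nuclear RNA list was lost (0.0541), as it was with regional scores in the fit (0.322). Without A53T vehicle replicate 1 the antigen presentation (0.233), cell cycle (0.0876) and reactive astrocyte (0.107) lists were lost, without replicate 2 the mitochondrially encoded (0.0804) and cell cycle (0.0654) lists, and without replicate 3 the thalamus (0.0548) and nuclear RNA (0.103) lists.

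**Figure D3:**
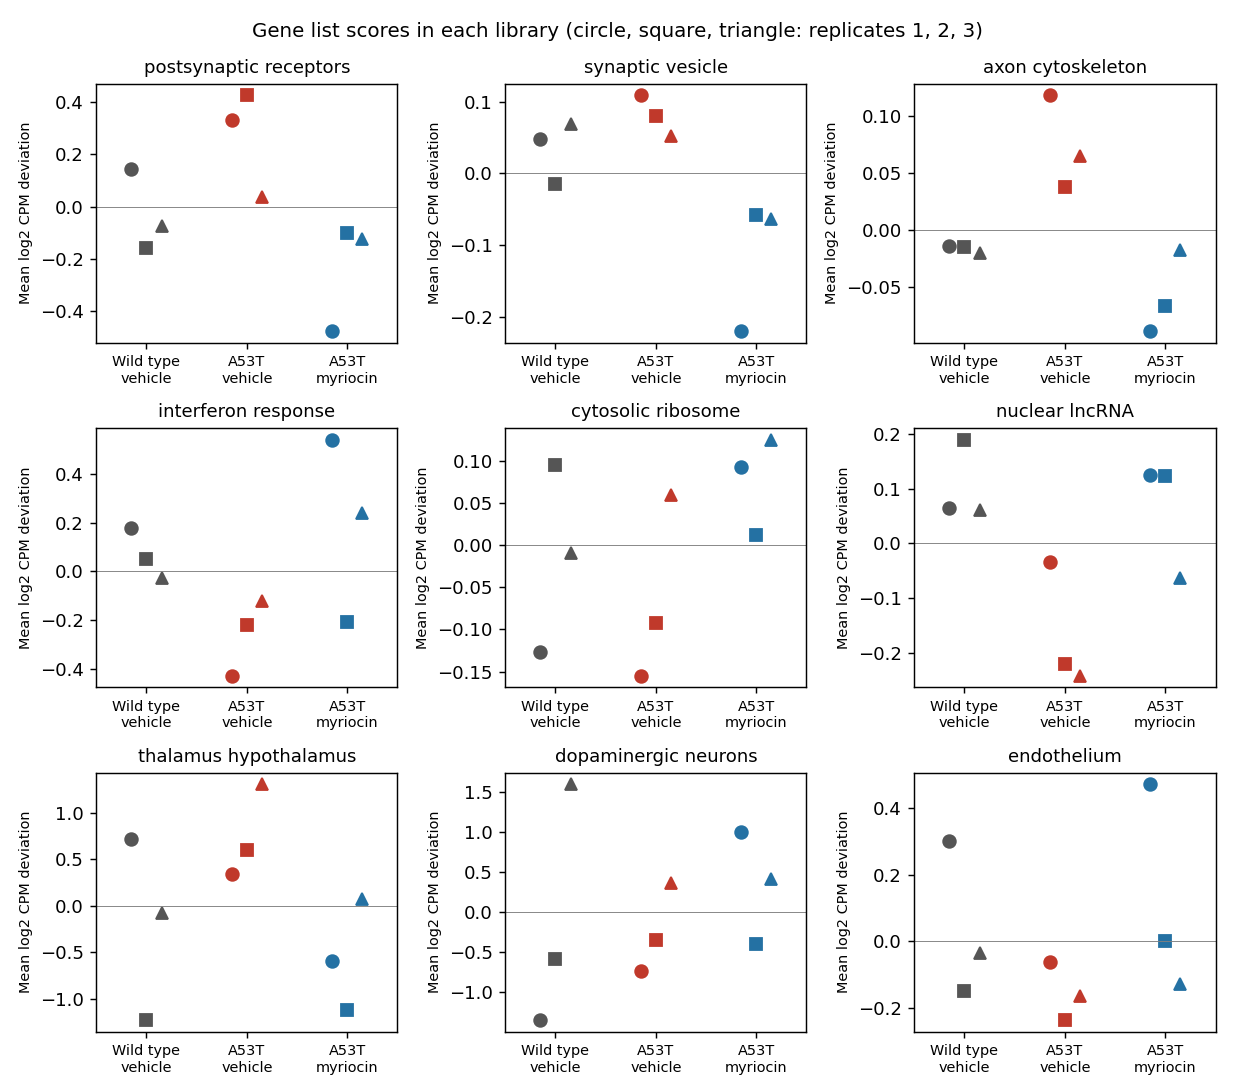
Scores of 9 gene lists in each library (vertical axes: mean deviation of the list's genes from their mean over the 9 libraries, in log2 CPM); circles, squares and triangles are replicates 1, 2 and 3. Axon cytoskeleton scores are above 0 in the 3 A53T vehicle libraries and below 0 in the 3 A53T myriocin libraries, while dopaminergic neuron scores range from -1.35 to 1.60 among the wild-type libraries.

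The comparison of A53T myriocin with wild type asks how far the transgenic midbrain given myriocin lies from the wild type given vehicle. Pttg1 fell 8.44-fold, to 1.91 ± 0.660 CPM (log2 fold change -3.08, SE 0.37, quasi-likelihood adjusted p = 0.0141), and Gbp11 fell 2.81-fold, to 1.96 ± 0.146 CPM (-1.49, SE 0.20, quasi-likelihood adjusted p = 0.0232). Hbegf, a growth factor of the epidermal growth factor family, rose 1.54-fold from 35.9 ± 0.396 to 55.2 ± 0.750 CPM (0.62, SE 0.09, quasi-likelihood adjusted p = 0.0400). Its mean was similar in A53T vehicle, 52.7 ± 4.43 CPM, 1.47-fold over wild type without passing (quasi-likelihood adjusted p = 0.0661). Myriocin against A53T vehicle gave a fold change of 1.05 for Hbegf (quasi-likelihood adjusted p = 0.793). In all 15 genes passed, 7 higher and 8 lower, and 992 genes (4.71%) had an unadjusted p under 0.05 where chance gives 1053. DESeq2 called 56 genes (58 with the filter on low counts), limma-voom 16 and edgeR without the filter on low counts 63. The number was 8, 9 and 4 without wild-type replicates 1, 2 and 3, and 5, 8 and 9 without A53T myriocin replicates 1, 2 and 3. Hbegf and Gbp11 were lost in each of these 6 fits (quasi-likelihood adjusted p 0.142 to 0.293 and 0.0718 to 0.173), and Pttg1 in each except that without wild-type replicate 1 (0.0521 to 0.0926).

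**Figure D4:**
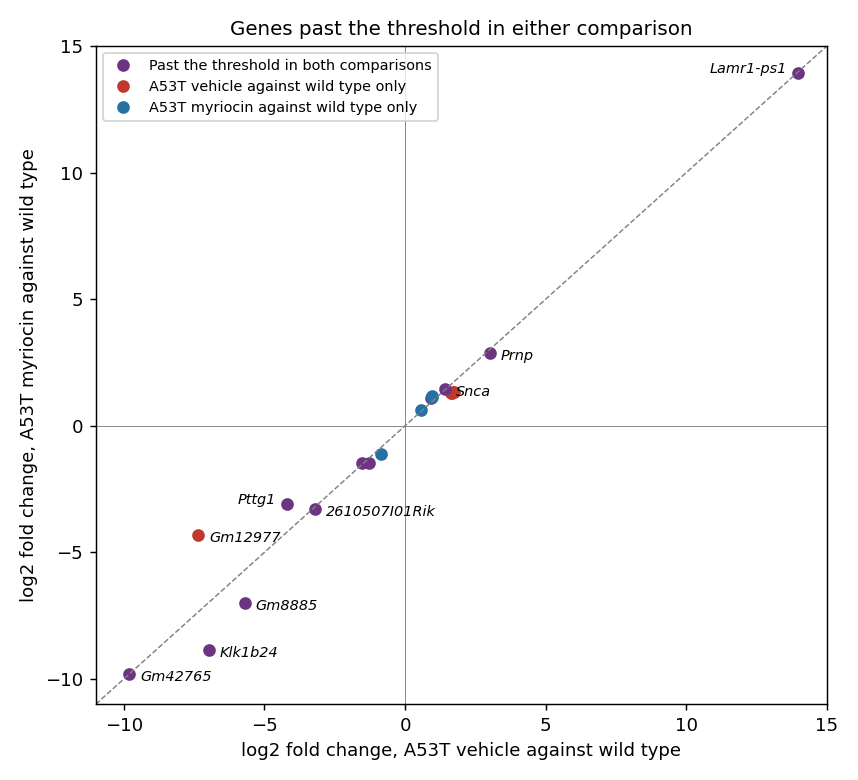
Fitted log2 fold changes of the 20 genes past the threshold in either comparison with wild type, A53T vehicle on the horizontal and A53T myriocin on the vertical axis, with the dashed line marking equal values. All 20 have the same sign in both; the fitted values of Lamr1-ps1 and Gm42765, at 0 counts in a whole group, depend on the prior count.

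Of the genes past the threshold in the 2 comparisons with wild type, 11 were shared, all with the same sign, where independent lists would share 0.00266 higher and 0.00304 lower genes. Groups simulated without effects, against a common simulated wild-type group, shared 0, which follows from the lack of effects. With genotype effects taken from the called genes and no myriocin effect, the simulated groups shared 11.95 (10 to 14 over 20 simulations). Both simulated A53T groups were given the same effects, so this number largely follows from the set-up too. The covariance of the 2 sets of log2 fold changes was 0.0803, against 0.0688 in the simulation without effects and 0.0927 in that with the genotype effects; their correlation, 0.400, was below both (0.498 and 0.572). With 3 wild-type libraries the controls could not be split, so part of the sharing may come from them. Pseudogenes made up 8 of the 20 genes called in either comparison, against 6.72% of the genes tested.

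In A53T myriocin against wild type 13 lists passed by camera with its preset correlation, 8 higher and 5 lower. With an estimated correlation all 13 had adjusted p = 0.967, and none passed with fry (smallest adjusted p 0.969). Cytosolic ribosome genes were higher for 70 of 75 members (median log2 fold change 0.11, camera adjusted p = 9.22e-05), respiratory chain genes for 56 of 64 (0.09, 0.00033) and proteasome genes for 27 of 31 (0.10, 0.00909), such as Rpl5, Cox5b at 238 ± 19.1 against 196 ± 2.22 CPM, and Psmd4. Homeostatic and disease-associated microglia genes were higher for 21 of 24 and 23 of 27 members (0.26, 0.00889 and 0.34, 0.017), with C1qb at 29.1 ± 14.9 against 14.6 ± 3.40 CPM and Itgax at 3.75 ± 3.27 against 1.42 ± 0.341 CPM. Interferon response genes were higher for 22 of 30 (0.20, 0.0441), with Usp18 at 3.20 ± 0.907 against 1.59 ± 0.288 CPM. Choroid plexus genes were higher for 17 of 18 (0.65, 0.00324); Ttr measured 228 ± 357 against 24.1 ± 21.5 CPM, with 640 CPM in A53T myriocin replicate 3. Cerebellar genes were higher for 9 of 14 (0.16, 0.0191), with Cbln3 at 2.90 ± 1.90 against 0.545 ± 0.170 CPM. Lower were postsynaptic receptor genes (28 of 35, -0.18, 0.00351), synaptic vesicle genes (22 of 30, -0.13, 0.00666), mitochondrially encoded genes (11 of 13, -0.32, 0.000938), oligodendrocyte precursor genes (13 of 15, -0.17, 0.0441) and haemoglobin and other erythroid genes (6 of 7, -0.93, 0.0203), with Gabra2, Synj1, mt-Nd5, Gpr17 and Hbb-bt as examples. Adjusted over the list alone, 2 mitochondrially encoded genes and 1 cerebellar gene passed, and 0 of the other 11 lists; among all genes tested no member passed.

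At an unadjusted p under 0.05, 1 list passed with an estimated correlation and 0 with fry. No list passed in every fit that left out 1 library. The number of lists was 7 without wild-type replicate 2 and 8, 26 and 7 without A53T myriocin replicates 1, 2 and 3. Without wild-type replicate 1 the ribosome (camera adjusted p = 0.178), proteasome (0.0973), respiratory chain (0.0973), synaptic vesicle (0.0736) and postsynaptic (0.0736) lists were lost. Without wild-type replicate 2 the homeostatic (0.766) and disease-associated microglia (0.339), interferon (0.185), choroid plexus (0.0776), cerebellum (0.359), mitochondrially encoded (0.142) and erythroid (0.322) lists were lost. Without wild-type replicate 3 the proteasome (0.269), respiratory chain (0.0645), interferon (0.125) and oligodendrocyte precursor (0.737) lists were lost. Without A53T myriocin replicate 1 the microglial (0.503 and 0.119), interferon (0.968), synaptic vesicle (0.340), postsynaptic (0.572) and oligodendrocyte precursor (0.119) lists were lost. Without replicate 2 the cerebellum (0.0849), oligodendrocyte precursor (0.121) and erythroid (0.158) lists were lost. Without replicate 3 the choroid plexus (0.823), microglial (0.266 and 0.904), proteasome (0.340), respiratory chain (0.0921), mitochondrially encoded (0.390), interferon (0.233), oligodendrocyte precursor (0.0921) and erythroid (0.173) lists were lost.

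Whether genes that differed between A53T vehicle and wild type moved back with myriocin was read from the signs of both comparisons. Such differences need not come from the transgene. Of the 16 genes changed in A53T vehicle against wild type, 9 had a myriocin effect of the opposite sign, 56.25%, and Gm42765, with 0 counts in all 6 A53T libraries, had none. With the 4 Ccl21 copies, all among the 9, counted as 1 gene (chosen after seeing the data) it was 6 of 13. Pttg1 was among them, with 0.878 ± 0.549 CPM in A53T vehicle and 1.91 ± 0.660 CPM in A53T myriocin, as were Prnp and Gbp11, the latter with 1.91 ± 0.275 and 1.96 ± 0.146 CPM. Snca was not. Because both comparisons use the A53T vehicle libraries with opposite signs, chance alone gives opposed changes: simulated data with the genotype effects and no myriocin effect gave 47.7% (16.7 to 80 over 20 simulations). At an unadjusted p under 0.01, 415 of 449 genes (92.4%) were opposed, against 91.8% (88.7 to 95.5) in groups simulated without any effect and 87.0% (84.0 to 92.3) in those with the genotype effects alone. Over all tested genes the covariance of the 2 sets of log2 fold changes was -0.155, against -0.0695 (-0.0755 to -0.0652) in groups simulated without effects. The correlation across genes, which are not independent replicates, was -0.645 against -0.502 (-0.530 to -0.477). Opposed signs made up 74.0% of all tested genes, against 66.7% (65.9 to 67.7). These observed values lie outside the simulated ranges. The simulated genes varied independently of each other, so the ranges leave out spread shared between genes.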

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

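Fits with regional scores, without the 3 libraries with Th under 15 CPM, and without A53T vehicle libraries 1 and 2, the count of Ccl21 copies as 1 gene, and DESeq2 with the filter on low counts, were chosen after the data were seen; the cause of a change was not tested unless stated. With 3 libraries a group, 8 to 12% of genes changed by 0.5 on the log2 scale were recovered in simulated data. Prnp passed in every alternative, with log2 fold changes of 2.93 to 3.07 in A53T vehicle and 2.84 to 2.96 in A53T myriocin against wild type. Over the genes named by the rule or called, with Snca and Prnp against wild type left out, 3983 values kept direction and side of the threshold. Besides these, 187 lost a call, 101 gained one and 17 reversed. Most of the 3983 belong to genes called in neither fit, and only genes called in the main fit could lose a call. Snca against wild type lost its call 9 times among the alternatives set before the data were examined. For the lists that passed, 350 values kept direction and call, 172 lost the call and 3 reversed.

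Against wild type, A53T vehicle had 16 changed genes and A53T myriocin 15; the numbers were 93 and 56 with DESeq2 on all genes with counts, 90 and 58 with DESeq2 and the filter, 135 and 63 with no filter, 25 and 16 with limma-voom, 11 and 8 with only the 2 groups compared, 5 and 6 with regional scores, 2 and 2 without the low-Th libraries, and 2 and 8 without A53T vehicle libraries 1 and 2. Leaving out 1 library gave 4 to 21 and 4 to 9, and upper-quartile scaling split the first count into 8 higher and 11 lower (42.1% higher against 50%). For A53T myriocin against A53T vehicle the count of 0 became 572 and 587 with DESeq2 without and with the filter, 702 with no filter and 0 to 92 without 1 library; limma-voom gave 0, and 2767 genes had an unadjusted p under 0.05. The numbers of lists, 6, 16 and 13 in the 3 comparisons, became 0, 0 and 0 with camera and an estimated correlation and with fry (unadjusted p under 0.05: 2, 1 and 1, and 2, 7 and 0). They ranged over 4 to 12, 8 to 28 and 7 to 26 without 1 library. Regional scores gave 16 in the first, of which only 4 were among the 6 lists of the main fit.

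Snca's log2 fold changes of 1.41 and 1.45 were 1.22 to 1.56 and 1.25 to 1.57 without 1 library (quasi-likelihood adjusted p 0.00834 to 0.113 and 0.00611 to 0.0926). They were 1.41 and 1.45 with only the 2 groups compared (0.0651 and 0.127), 1.17 and 1.22 without the low-Th libraries (0.940 and 0.550), and 1.46 and 1.43 without A53T vehicle libraries 1 and 2 (0.560 and 0.177); fewer libraries leave fewer degrees of freedom. Opposed changes were 56.25% of genes, 40 to 75% without 1 library, 46.2% with the 4 Ccl21 copies counted as 1 gene and 92.4% at an unadjusted p under 0.01, where groups simulated without effects gave 91.8% and those with the genotype effects alone 87.0% (84.0 to 92.3).

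These log2 fold changes reversed; the genes passed in neither fit. In A53T vehicle against wild type Pitx3 turned to 0.86 and Sall1 to 0.0090 without wild-type replicate 3 (ranges without 1 library -2.24 to 0.86 and -0.45 to 0.0090), Trem2 to -0.032 with regional scores and Mobp to -0.040 without the low-Th libraries. In A53T myriocin against A53T vehicle Snca turned to -0.0033 and -0.035 without A53T myriocin replicates 1 and 3 (range -0.035 to 0.14) and to -0.026 without A53T vehicle libraries 1 and 2, where the ribosome list's median was -0.0049; with regional scores Smpd3 turned to 0.011, Sncg to -0.17 and Calb1 to 0.14. In A53T myriocin against wild type Sox6, Foxa1 and Lmx1b turned to 0.016, 0.57 and 0.83 without wild-type replicate 3 (lowest -0.40, -1.18 and -1.17), Calb1 and Cbln1 to -0.12 and -0.031 without replicate 2 (highest 0.41 and 0.58), Ttr to -0.20 without A53T myriocin replicate 3 (highest 4.29) and Calb1 to -0.028 without the low-Th libraries. There the tests, not the medians, of 2 lists turned: interferon response without A53T myriocin replicate 1 (median 0.041, range 0.041 to 0.39) and homeostatic microglia without the low-Th libraries (median 0.023).

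With the replicate number as a block, 6, 0 and 8 genes and 8, 21 and 13 lists passed; the interferon and oligodendrocyte precursor lists were lost in A53T myriocin against wild type (camera adjusted p = 0.0522 and 0.0617). Deviations of libraries sharing a number did not go together in all pairs (correlations -0.177 to 0.282). With 3 libraries a group, these correlations cannot tell whether the numbers pair the samples.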

Other observations

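The tests of strain segments, of dopaminergic loss, of dissection and of single pairs of libraries, and all genes named here, were chosen or revised after the result was seen; the tests of gene copies and of regional scores were written before their values.

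Single libraries carried markers of tissue next to the midbrain. Ttr, transthyretin of the choroid plexus, measured 640 CPM in A53T myriocin replicate 3 and 184 CPM in A53T vehicle replicate 2, against at most 63.8 CPM in the other 7 libraries. The same A53T myriocin library had the highest score of the glucocorticoid response list (0.66, against -0.31 to 0.02 in the others). Prl, prolactin of the pituitary, measured 39.3 CPM in A53T vehicle replicate 3 and 37.6 CPM in A53T myriocin replicate 1, and 0 to 6.37 CPM elsewhere. Gfap, an astrocyte gene, ranged from 100.04 to 509 CPM among wild-type libraries, and Mbp, a myelin gene, from 2505 to 3689 CPM over all 9. Xist had 2244 to 4478 counts in each library and 4 Y-linked genes had at most 3 counts together, the pattern of female mice.

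Besides Prnp, Snca and Lamr1-ps1, 17 genes changed in 1 or both comparisons with wild type. The 2 regional scores did not account for the size of these changes. With the scores in the fit the median size of the log2 fold changes in A53T vehicle was 0.952 of that without (1.60 against 1.68). Of the genes 17 of 17 kept their sign. Of 13 calls 2 remained, as the median SE went from 0.215 to 0.257 and the degrees of freedom from 6 to 4. Genes that pass vary little within groups, so they could hardly follow scores that vary within groups. Other regions were not in the fit, so the ratio does not decide on regional make-up as a whole. Reads shared between near-identical copies are a candidate explanation for part of the 17 genes. Of these 10 have such a copy, where random genes of like expression gave a median of 3. Among the 10 are Ccl21b, Gm21541, Gm13304 and Gm10591, which are copies of each other and here count as 4 genes. Rpl26, at 277 ± 30.2 CPM in wild type and 179 ± 9.39 CPM in A53T vehicle, and its copy Gm15772 went opposite ways in A53T vehicle. Their sum was 460 ± 50.9 CPM in wild type, 525 ± 30.5 CPM in A53T vehicle (1.14 times wild type) and 598 ± 32.6 CPM in A53T myriocin (1.30 times wild type), where Gm15772 was called too, so reads moving between these 2 genes alone do not account for the values with myriocin; 3 other copies were not summed. Segments of another strain around the transgene or elsewhere may also differ. With changed genes within 1 Mb of each other counted once, the 17 genes lay in 14 separate places. Of these places 4 had another within 20 Mb. Random draws of 17 genes, joined in the same way, gave a median of 4 and a 95th percentile of 7. The bound first set against such segments (at or below the median) was met and then replaced by the 5th percentile, because scattered segments need not crowd. Segments therefore cannot be told apart from other causes. An effect of alpha-synuclein on these genes stays open, untested.

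Dopaminergic markers differed between libraries within groups: the SD of the list's score was 1.53 among wild-type libraries, 0.540 without wild-type replicate 3, and 0.558 among A53T vehicle libraries. The wild-type mice carry no transgene, so loss of neurons in A53T mice has no bearing on the spread among them; this follows from the genotype and was not tested. Among A53T vehicle libraries the SD was 0.365 times that of wild type (95% interval 0.058 to 2.28), too wide to tell loss that differs between A53T animals apart from other causes; this test replaced others set earlier. Different tissue taken at dissection is a candidate explanation, since the median within-group SD of region lists was 4.82 times that of glial lists (0.721 against 0.150). The region lists included serotonergic neurons and red nucleus and colliculus, written as cell types. They left out choroid plexus (within-group SD 0.596) and pituitary (2.03), written as other regions. Left out of the glial lists were, among others, reactive astrocytes (0.488) and disease-associated microglia (0.361), so the ratio depends on the lists taken. Part of this ratio goes with expression level. Random lists matched on expression had a median SD of 0.0828 to 0.263 for the region lists and 0.0467 to 0.0539 for the glial lists. In that ratio 7 of 7 region lists, and also 4 of 4 glial lists, lay above the 95th percentile of random lists. A loss of neurons of a size hidden by this spread stays open.

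Between A53T myriocin and A53T vehicle libraries 16 lists passed by camera with its preset correlation, and 0 with an estimated correlation or with fry. With regional scores in the fit a share of 0.8 of the 15 other lists (12) still passed in the same direction, and calcium signalling, clock and nuclear RNAs did not; this lies on the bound of 0.8 set against regional make-up as the cause and, by its binomial SE of 0.103, not beyond it, a spread that was taken into account only after the value was seen. Without A53T vehicle replicates 1 and 2, 0.4375 of the 16 lists (7) still passed, under the 0.5 first set for these libraries as the cause; other pairs, compared afterwards, left 4 to 14, and 0.25 without A53T myriocin replicates 1 and 3. Neither can be told apart from an effect of myriocin, because the first share lies on its bound and another pair left fewer lists than the second. The covariance of the genotype and myriocin fold changes was as low as observed (-0.138 on log2 CPM) in 25 of 840 groupings of the 9 libraries (one-sided exact p = 0.0298, chosen after seeing the data), and dissection could add to it.

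The 10 splits of 6 libraries into 3 and 3 are too few to show that a number exceeds chance, but can show that other splits reach it. Genes numbered 16, 0 and 15 in the 3 comparisons, with at most 0 in the other splits, and 1, 10 and 1 splits gave as many. Lists numbered 6, 16 and 13, with up to 20, 34 and 33 in another split, and 9, 4 and 8 splits, the real one included, gave as many. The numbers of lists were thus no larger than mixed groups can give.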
